A study of Arabidopsis with 12 samples.

How the data were processed

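Total RNA of Arabidopsis flu and flu toc33-1 seedlings was sequenced on a DNBSEQ-T7 instrument with the provider's standard workflow, per the labels' protocols. The sample titles and the growth protocol give an age of 7 d, while the design text of the series gives an age 1 d lower. The labels call the material seedlings in the titles and leaf in the tissue field, so the tissue is taken only as far as that. Groups were read from the sample titles, genotype and treatment labels, with 3 libraries in each of 4 groups, and replicate numbers from the titles.

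The authors deposited 1 table of transcript abundances in TPM for 48359 transcripts and 12 libraries, and every library's column has the same sum. Per the submitters' processing notes, kallisto 0.46.2 and sleuth 0.30.0 were used with TAIR10; which transcript set was indexed, strand settings and filters are not given in the sources used here. The deposited TPM values are scaled within each library by the authors, so they are shares of the transcripts of a library and not amounts per cell, and a large rise of some genes lowers the values of the rest. A few genes did not dominate: the 100 most abundant genes took 18.4% to 24.1% of TPM, and transcripts of the plastid genome 0.349% to 0.544%. TPM carries no depth, so no interval for counting error or limit of detection can be given. Reads that fit near-identical copies are shared out by the abundance estimate, which makes single members of such families uncertain. Polyadenylation or other selection before sequencing is not given in the sources used here, which limits what transcripts of organelle genomes show.

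Transcripts were summed to 27655 genes by locus. Names came from a table of RefSeq genes of assembly TAIR10.1, in which 27445 loci were found; its coordinates were not used because the files name TAIR10. All 363 entries of the gene lists were found in the file, and 344 of their symbols in that table, the rest being given by locus. Values were analysed as log2(TPM + 1), a pseudocount of 1 TPM. Genes at 1 TPM or more in at least 3 libraries were tested, 19667 genes or 71.1%. A gene whose libraries in a group are all 0 is described as listed at 0, with no fold.

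The test was limma 3.58.1 in R 4.3.3, a linear model of the 4 group means over all 12 libraries with moderated, two-sided tests and a trend of the spread with mean level, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The planned design held a branch for counts, which did not apply because the values are TPM; the branch written for TPM was used. There were 4 comparisons of groups (light against dark in each genotype, flu toc33 against flu in each treatment), the difference of the light response between genotypes as an interaction, and the mean light response. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 26 lists of a comparison. With the preset correlation 12, 11, 14 and 19 lists were called in the 4 comparisons, 8 in the interaction and 12 for the mean response, and with the estimated correlation 5, 5, 9, 8, 3 and 6. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

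The design, alternatives, rule for named genes and gene lists were fixed before the data were examined. The lists hold early singlet oxygen response genes and singlet oxygen signalling components, jasmonate, salicylic acid and EDS1, and ethylene genes, heat shock, light-harvesting proteins, nuclear photosystem and electron transport, Calvin cycle, tetrapyrrole synthesis, plastid protein import, plastid chaperones and Clp, light signalling and photoprotection, flavonoid synthesis, circadian clock, dark and starvation response, antioxidant enzymes, electrophile detoxification, indole and aliphatic glucosinolate synthesis, root, guard cell, epidermis and vascular markers, and the plastid and mitochondrial genomes. Genes were named by rule: TOC33, FLU, EX1 and EX2; for each comparison of groups the 8 largest rises and falls among genes called with at least a 2-fold change, groups without overlap and a mean of at least 5 TPM in the higher group; the 8 largest interactions each way with at least 5 TPM in the highest group; and up to 4 members of each list with the smallest p in a comparison. For other genes the text says when they were chosen.

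Alternatives were pseudocounts of 0.1 and 5 TPM, no filter on low values or a filter at 5 TPM, quantile normalization, median-ratio scaling, removal of organelle genes, the replicate number as a block, a robust spread, fits of the compared groups alone, 28938 transcripts tested singly, a 2-fold threshold and leaving out each library. The model was tested on simulated data in which all 4 groups were drawn around the flu dark means with each gene's replicate spread. Of the 19085 genes tested there, 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold, in flu light only. Noise was drawn for each gene alone and few genes changed, so shifts of scaling and correlation between genes were not covered. For flu light against flu dark the model called 80.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 9 unchanged genes. For the interaction it called 58.2%, 76.1% and 98.5% at these sizes, and 5 unchanged genes. At most 71 genes held identical values in any pair of replicates. All 12 libraries were used.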

Results

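The study measured transcripts of Arabidopsis seedlings in 12 RNA-seq libraries, 3 in each of 4 groups. The flu mutant lacks a brake on tetrapyrrole synthesis, so that protochlorophyllide accumulates in the dark and singlet oxygen forms in the plastid when the light returns. The flu toc33 double mutant carries toc33-1 as well, an allele of the gene for TOC33, a receptor GTPase of the chloroplast outer membrane through which precursor proteins are imported. Seedlings of both genotypes grew in continuous light and were kept dark for 4 h (flu dark, flu toc33 dark), or dark for 4 h and then lit for 1 h (flu light, flu toc33 light). The series' title names TOC33 as a relay of the signal that singlet oxygen sends from the chloroplast to the nucleus, and the comparisons below ask how the nuclear response to light differs without it. No wild type was analysed here, so the response of flu holds the effects of light and of singlet oxygen together. The lit groups were also sampled 1 h later than the dark groups, and no group stayed dark for that hour. Time and clock phase therefore cannot be told apart from light, and light response below means the difference of lit and dark groups.

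Values are TPM, the share of each transcript among all transcripts of a library corrected for its length, summed per gene. Every library has the same sum by construction, so the number of reads behind a value is unknown and no counting error can be given. Between 18533 and 19023 genes per library stood at 1 TPM or more, and 19667 genes were tested. Replicates correlated across genes at 0.992 to 0.996 on the log2 scale. The median absolute log2 difference between replicates was 0.0653 to 0.155, and the pairs with flu dark replicate 3 gave the highest values, 0.155 and 0.152. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the scale of log2(TPM + 1) and understate the change of genes at low TPM. A list is called at an adjusted p under 0.05 from limma's camera, and counts of its members rest on limma with Benjamini-Hochberg adjustment over all genes tested. The libraries differed between genotypes and treatments along the first 2 principal components, which held 60.1% and 27.5% of the variance.

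The targeted gene was measured first. TOC33 (AT1G02280) stood at 203 ± 11.1 TPM (SD, n = 3) in flu dark, 172 ± 2.71 TPM in flu light, 48.7 ± 0.631 TPM in flu toc33 dark and 3.97 ± 0.271 TPM in flu toc33 light. The double mutant held 23.9% of the flu level in the dark and 2.31% of it in the light, and its 3 dark libraries stood at 48.4, 48.2 and 49.4 TPM. In limma with Benjamini-Hochberg adjustment TOC33 was lower in flu toc33 by a log2 of -2.04 ± 0.0484 (SE) in the dark (adjusted p = 3.65e-12) and of -5.12 ± 0.0484 in the light (adjusted p = 2.96e-16). TOC33 was lower than in flu in every library of the double mutant, with a residual transcript in the dark that fell in the light by a log2 of 3.32 (limma, adjusted p = 9.08e-16). TOC34, the paralog of TOC33, was added after the TOC33 values were seen and before its own were, and stood at 28.9 ± 1.94 TPM in flu toc33 dark and 39.5 ± 0.891 TPM in flu toc33 light. FLU (AT3G14110), the brake itself, was transcribed in all groups, at 185 ± 9.04 TPM in flu dark, 169 ± 3.3 TPM in flu light, 215 ± 8.94 TPM in flu toc33 dark and 207 ± 2.55 TPM in flu toc33 light. EX1 (AT4G33630), a plastid protein needed for the singlet oxygen response, stood at 52.5 ± 7.77, 60.6 ± 1.63, 64.5 ± 0.981 and 65.3 ± 3.1 TPM in the same order. EX2 (AT1G27510), its relative, stood at 84.3 ± 3.42, 75.4 ± 3.31, 109 ± 1.79 and 62.5 ± 1.39 TPM, and its light response was lower in flu toc33 by a log2 of -0.63 ± 0.0596 (limma, adjusted p = 8.56e-07).

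**Figure D1:**
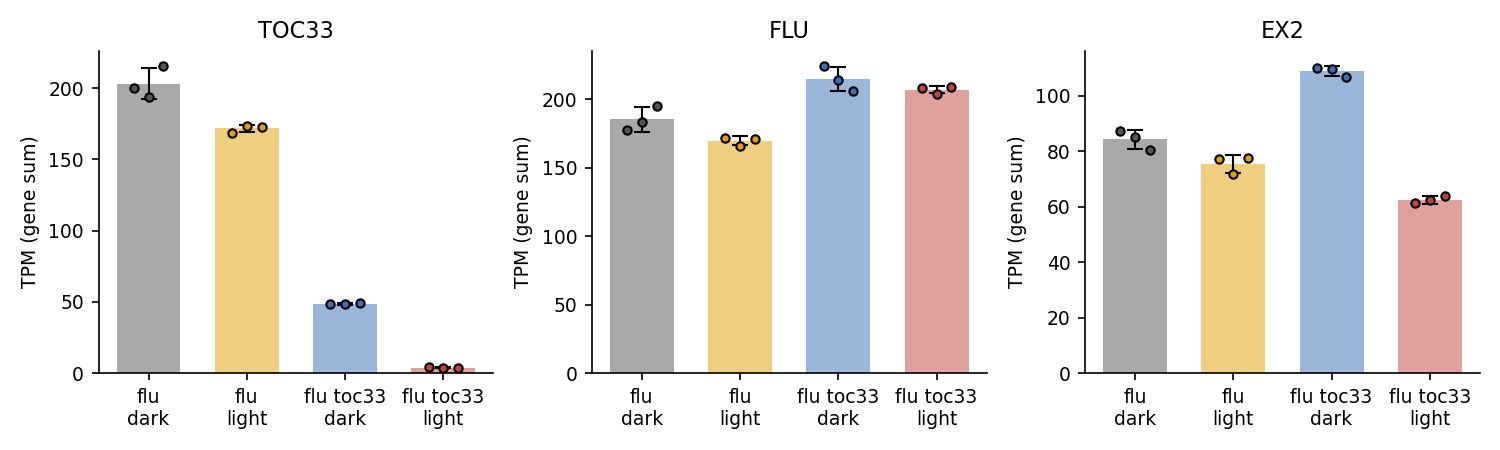
TPM of TOC33, FLU and EX2 in the 12 libraries. Bars are group means, error bars are SD (n = 3) and points are libraries; TOC33 is at 203 TPM in flu dark, 48.7 TPM in flu toc33 dark and 3.97 TPM in flu toc33 light.

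The first comparison asked what 1 h of light changed in flu. The largest rises were from near 0 in the dark. DIP2 (AT5G03210) rose from 0.838 ± 0.274 TPM (SD, n = 3) in flu dark to 416 ± 3.3 TPM in flu light, PUB19 (AT1G60190), a U-box ubiquitin ligase, from 0.372 ± 0.151 to 175 ± 2.08 TPM, and FBS1 (AT1G61340), a stress-induced F-box protein, from 3.44 ± 0.945 to 426 ± 9.28 TPM. WRKY30 (AT5G24110), a WRKY transcription factor, rose from 0.854 ± 0.213 to 149 ± 5.41 TPM, ERF53 (AT2G20880), a transcription factor of the ethylene response factor family, from 0.325 ± 0.168 to 98.5 ± 5.93 TPM, and AT1G20070 from 3.39 ± 0.953 to 296 ± 11.9 TPM. ERF105 (AT5G51190), of the same family as ERF53, was listed at 0 in all 3 flu dark libraries and stood at 164 ± 5.21 TPM in flu light. MYC2 (AT1G32640), a transcription factor of jasmonate signalling, was at or near 0 in the 3 flu dark libraries and at 72.8 ± 2.1 TPM in flu light, so no fold is given for these genes. The log2 changes of the others ran from 6.10 for AT1G20070 to 7.84 for DIP2.

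The falls in flu were smaller than the rises. CIB1 (AT4G34530), a transcription factor that interacts with cryptochrome, fell from 32.1 ± 1.42 to 0.937 ± 0.981 TPM, and the SAUR genes AT4G34770 and AT4G34790, of a family induced by auxin, fell from 29.8 ± 0.97 to 0.892 ± 0.423 TPM and from 16.3 ± 1.73 to 0.552 ± 0.236 TPM. AT5G19120 fell from 342 ± 24.1 to 33.5 ± 0.222 TPM, AT2G20670 from 418 ± 13.2 to 43.3 ± 0.95 TPM, AT4G10270 from 37.6 ± 4.68 to 3.66 ± 0.722 TPM, and the seed storage gene CRU3 (AT4G28520) from 19.1 ± 1.9 to 1.31 ± 0.362 TPM. AT2G44130 stood at 10.7 ± 2.46 TPM in flu dark and was listed at 0 in the 3 flu light libraries.

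All 40 measured genes of the early singlet oxygen list rose in flu, with a median log2 change of 3.23 (camera, adjusted p = 5.62e-27). The zinc finger genes ZAT6 and ZAT12 rose by a log2 of 4.86 ± 0.0549 (SE) and 5.16 ± 0.0637, WRKY33 by 4.05 ± 0.0539 and NAC102 by 2.80 ± 0.0361. The median includes ERF105, which is listed at 0 in flu dark. Of 17 heat shock genes 16 rose and 1 fell, with a median of 2.64 (camera, adjusted p = 1.02e-08). They included the heat shock factor HSFA2 (AT2G26150) at 5.53, HSP70 (AT3G12580) at 5.28 and HSP90.1 at 3.97. Light signalling and photoprotection genes rose in 10 of 11 cases and fell in 1, with a median of 1.82 (camera, adjusted p = 4.24e-07). They included SIG5, a plastid sigma factor, at 4.14, ELIP2 at 5.12 and BBX31 at 5.86. Electrophile detoxification genes rose in 17 of 21 cases and fell in 2, with a median of 1.16 (camera, adjusted p = 4.24e-07). They included the glutathione transferase GSTF8 at 2.27 and the alternative oxidase AOX1A at 2.12. Dark and starvation genes fell in 14 of 15 cases and rose in 1, with a median of -1.19 (camera, adjusted p = 1.45e-06). They included AKINBETA1, a subunit of the SnRK1 kinase, at -1.44 and BT2 at -2.39. These 5 lists were also called with an estimated correlation, with adjusted p = 4.92e-04, 0.00774, 0.00548, 0.00548 and 0.0135 in the order given.

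The other calls in flu were lost with an estimated correlation. All 10 clock genes rose, with a median of 0.98 (camera, adjusted p = 8.55e-07; adjusted p = 0.127 with an estimated correlation). Leading members were PRR9 at 5.38 and GI at 4.02. Flavonoid synthesis genes rose in 6 of 7 cases, with a median of 1.12 (camera, adjusted p = 6.98e-04; adjusted p = 0.0573 with an estimated correlation). The leading member was F3H, flavanone 3-hydroxylase, at 3.37. Of 25 jasmonate genes 14 rose and 6 fell, with a median of 0.27 (camera, adjusted p = 0.0071; adjusted p = 0.205 with an estimated correlation), and LOX3 and AOC3, which encode enzymes of jasmonate synthesis, rose by 3.38 and 3.61. In the salicylic acid and EDS1 list 8 of 13 genes rose and 2 fell, with a median of 0.79 (camera, adjusted p = 0.0153; adjusted p = 0.153 with an estimated correlation). Leading members were CBP60G at 2.81 and EDS1 at 2.19; the call was also lost with no filter on low values, at a median of 0.76 (adjusted p = 0.0531). All 6 root markers fell, with a median of -0.84 (camera, adjusted p = 0.0153; adjusted p = 0.0824 with an estimated correlation). Of 18 genes of light-harvesting proteins 14 fell and 3 rose, with a median of -0.28 (camera, adjusted p = 0.0269; adjusted p = 0.751 with an estimated correlation). Of 29 nuclear photosystem and electron transport genes 19 fell and 2 rose, with a median of -0.14 (camera, adjusted p = 0.0211; adjusted p = 0.75 with an estimated correlation). The calls of the light-harvesting and photosystem lists were also lost under quantile normalization, under median-ratio scaling and without flu dark replicate 3 or flu light replicate 3. Quantile normalization brought the medians to -0.13 and -0.00283, with adjusted p = 0.4996 and 0.635, and median-ratio scaling to -0.25 and -0.11, with adjusted p = 0.103 and 0.171. Without flu dark replicate 3 the medians were -0.21 and -0.0762, with adjusted p = 0.0576 and 0.0739 from camera, and without flu light replicate 3 they were -0.27 and -0.13, with adjusted p = 0.0539 and 0.0519. Adjusted over the list alone, the counts of all lists named for this comparison were the same, except that 20 photosystem genes fell.

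Over all genes, 12118 of 19667 were called in flu light against flu dark, 5547 higher and 6571 lower, by limma with Benjamini-Hochberg adjustment. At least a 2-fold change was seen in 2512 of them, 1799 higher and 713 lower. The groups did not overlap in 63.6% of genes, against 10% by chance. The direction split depended on scaling: quantile normalization gave 4691 higher and 8660 lower, and moved the median change of all genes from -0.0375 to -0.12, and median-ratio scaling gave 6091 higher and 5992 lower.

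The same light period was compared in flu toc33. Of the 8 largest rises, 7 were those of heat shock genes: HSP70 rose from 4.46 ± 0.253 TPM (SD, n = 3) in flu toc33 dark to 861 ± 17.9 TPM in flu toc33 light, HSP17.6A (AT5G12030) from 0.399 ± 0.217 to 199.6 ± 7.73 TPM, HSP17.4 (AT3G46230) from 0.585 ± 0.0602 to 156 ± 3.38 TPM and the factor HSFA2 from 0.185 ± 0.113 to 117 ± 3.12 TPM. The genes of further small heat shock proteins AT5G51440 and AT1G07400 rose from 1.9 ± 0.114 to 344 ± 7.08 TPM and from 1.54 ± 0.279 to 292 ± 10.4 TPM. HSP17.6II (AT5G12020) was listed at 0 in the 3 flu toc33 dark libraries and stood at 161 ± 1.89 TPM in flu toc33 light. ELIP1 (AT3G22840), an early light-induced protein of thylakoids, rose from 2.73 ± 0.475 to 502 ± 9.17 TPM. The largest falls were those of AT3G15450, from 3465 ± 55.8 to 72.2 ± 0.837 TPM, AT1G28330, a dormancy-associated gene, from 1392 ± 14.6 to 52.8 ± 5.19 TPM, BXL1 (AT5G49360), a beta-xylosidase, from 984 ± 15.8 to 36.9 ± 0.787 TPM, and ERD5 (AT3G30775), proline dehydrogenase, from 632 ± 2.5 to 21.2 ± 1.4 TPM. AT4G36850, AT5G22920, MIOX2 (AT2G19800), a myo-inositol oxygenase, and PP2-A13 (AT3G61060) fell by a log2 of 4.77, 4.98, 4.91 and 4.85. Their flu toc33 dark levels were 491, 424, 259 and 238 TPM, and their flu toc33 light levels 17, 12.5, 7.64 and 7.29 TPM.

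Among the lists, 16 of 17 heat shock genes rose in flu toc33 and none fell, with a median log2 change of 5.65 (camera, adjusted p = 7.11e-10; adjusted p = 0.0103 with an estimated correlation). Dark and starvation genes fell in 14 of 15 cases and rose in 1, with a median of -3.82 (camera, adjusted p = 2.52e-10; adjusted p = 0.0103 with an estimated correlation). They included AKINBETA1 at -4.55 ± 0.0368 (SE), BCAT2, a branched-chain aminotransferase, at -3.94 ± 0.0467 and IVD, isovaleryl-CoA dehydrogenase, at -3.02 ± 0.0343. Light signalling and photoprotection genes rose in 9 of 11 cases, with a median of 2.51 (camera, adjusted p = 4.14e-05; adjusted p = 0.0118 with an estimated correlation), and all 7 flavonoid genes rose, with a median of 2.78 (camera, adjusted p = 1.72e-04; adjusted p = 0.0407 with an estimated correlation). CHS, chalcone synthase, rose by 2.78. Electrophile detoxification genes rose in 16 of 21 cases and fell in 1, with a median of 0.98 (camera, adjusted p = 1.06e-04; adjusted p = 0.0165 with an estimated correlation). They included UGT74E2 (AT1G05680), a glycosyltransferase, at 4.55 and AOX1A at 3.46.

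Of the early singlet oxygen list in flu toc33, 30 of 40 genes rose, 6 fell and 4 were not called, with a median of 0.58 (camera, adjusted p = 0.00145; adjusted p = 0.0849 with an estimated correlation). ZAT6 rose by 2.90 ± 0.0549 (SE) and ZAT12 by 2.57 ± 0.0637, while TCH4 and ERF1A changed by -1.95 ± 0.0438 and -1.68 ± 0.0445. The remaining calls were lost with an estimated correlation. Clock genes rose in 8 of 10 cases and fell in 2, with a median of 1.16 (camera, adjusted p = 0.00374; adjusted p = 0.475 with an estimated correlation). Plastid chaperone and Clp genes rose in 9 of 12 cases and fell in 2, with a median of 0.57 (camera, adjusted p = 0.00811; adjusted p = 0.204 with an estimated correlation). The rising genes included CPN60B2 at 2.24. Of 6 aliphatic glucosinolate genes 5 rose, with a median of 1.83 (camera, adjusted p = 0.00424; adjusted p = 0.196 with an estimated correlation). Ethylene genes fell in 10 of 15 cases and rose in 2, with a median of -0.63 (camera, adjusted p = 0.00374; adjusted p = 0.522 with an estimated correlation), EBF2 and EIL1 among them at -2.12 and -1.81. Photosystem and electron transport genes fell in 17 of 29 cases and rose in 5, with a median of -0.16 (camera, adjusted p = 0.0143; adjusted p = 0.707 with an estimated correlation), and that call was also lost under quantile normalization, at a median of -0.0971 (adjusted p = 0.302). Counts adjusted over the list alone were the same for all of these lists.

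Between flu toc33 dark and light 13964 of 19667 genes differed by limma with Benjamini-Hochberg adjustment, 7939 higher and 6025 lower in the light. Of these, 3147 changed at least 2-fold, 1798 up and 1349 down. The groups did not overlap in 77.5% of genes, against 10% by chance. Quantile normalization turned the split, to 6954 higher and 7177 lower.

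The genotypes were compared after 4 h of dark to ask what toc33-1 changed before the light returned. The largest falls included genes of plant defence. The plant defensin genes PDF1.2 (AT5G44420), PDF1.2c (AT5G44430) and PDF1.3 (AT2G26010) stood at 154 ± 12.9, 88.4 ± 7.94 and 181 ± 16.4 TPM (SD, n = 3) in flu dark and at 0.753 ± 0.262, 0.389 ± 0.00399 and 4.43 ± 1.33 TPM in flu toc33 dark. PR1 (AT2G14610), a pathogenesis-related gene of the salicylic acid response, stood at 33.3 ± 1.28 and 0.385 ± 0.0485 TPM. AT3G22235 stood at 38.7 ± 4.2 and 0.452 ± 0.438 TPM, AT4G12490 at 41.2 ± 0.495 and 2.53 ± 1.07 TPM, AT4G12495 at 33.7 ± 17.8 and 1.72 ± 1.25 TPM and AT1G13609 at 60.3 ± 3.43 and 5.01 ± 1.78 TPM. The defensin genes are near-identical copies, so how reads were split among them is uncertain.

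The 5 largest rises were those of seed storage genes. The albumin genes SESA1 (AT4G27140), SESA2 (AT4G27150), SESA3 (AT4G27160) and SESA4 (AT4G27170) stood at 175 ± 109.5, 166 ± 109, 145 ± 94.8 and 98.9 ± 67.5 TPM in flu toc33 dark and below 1 TPM in flu dark, at 0.354 ± 0.121, 0.182 ± 0.0613, 0.441 ± 0.0465 and 0.0395 ± 0.0685 TPM. The cruciferin gene CRU2 (AT1G03880) stood at 63.7 ± 43.4 and 0.0361 ± 0.0356 TPM and the oleosin gene OLEO1 (AT4G25140) at 58.6 ± 38.2 and 2.09 ± 0.37 TPM. These levels spread widely between the flu toc33 dark libraries: SESA1 stood at 271, 55.8 and 199 TPM in replicates 1, 2 and 3. Without flu toc33 dark replicate 2 the log2 change rose from 6.75 to 7.43 for SESA1, from 6.85 to 7.55 for SESA2, from 6.35 to 7.08 for SESA3, from 6.26 to 7.00 for SESA4, from 5.64 to 6.38 for CRU2 and from 3.98 to 4.68 for OLEO1. AT1G64795 was higher as well, at 48.9 ± 14.8 against 1.5 ± 2.59 TPM, with a log2 change of 4.77 that became 5.59 without flu dark replicate 2. AT1G31095 stood at 21 ± 2.1 against 0.679 ± 1.18 TPM.

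**Figure D2:**
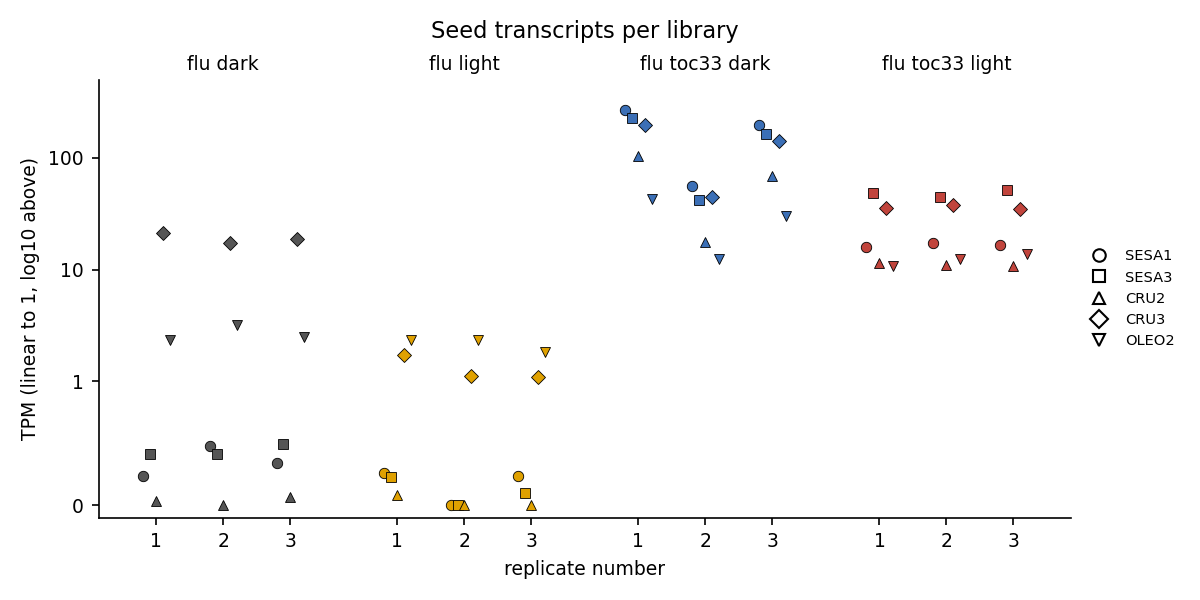
TPM of 5 seed genes in each of the 12 libraries, with replicate number on the x axis and TPM on the y axis, linear to 1 and log10 above. Every point is a library; SESA1 runs from 55.8 to 271 TPM in flu toc33 dark and has a mean of 16.7 TPM in flu toc33 light, and is below 1 TPM in flu.

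Electrophile detoxification genes were lower in flu toc33 dark in 20 of 21 cases and higher in 1, with a median log2 difference of -1.23 (camera, adjusted p = 6.74e-17; adjusted p = 5.89e-04 with an estimated correlation). UGT74E2 differed by -3.20 ± 0.0498 (SE), CYP81D8 by -2.33 ± 0.0601, OPR1 by -1.73 ± 0.0376 and AOX1A by -1.62 ± 0.0398. Jasmonate genes were lower in 18 of 25 cases and higher in none, with a median of -0.54 (camera, adjusted p = 2.26e-07; adjusted p = 0.0282 with an estimated correlation). They included AOC2 at -1.95 and LOX2 at -1.99, both of jasmonate synthesis. Genes of the salicylic acid and EDS1 list were lower in 10 of 13 cases and higher in 2, with a median of -0.65 (camera, adjusted p = 6.58e-04; adjusted p = 0.0499 with an estimated correlation). Indole glucosinolate and camalexin genes were lower in 8 of 10 cases, with a median of -0.67 (camera, adjusted p = 2.26e-07; adjusted p = 0.0244 with an estimated correlation). They included PAD3, the last enzyme of camalexin synthesis, at -2.07. Aliphatic glucosinolate genes were lower in 5 of 6 cases, with a median of -0.85 (camera, adjusted p = 6.73e-06; adjusted p = 0.0292 with an estimated correlation). The early singlet oxygen list was lower already in the dark, in 22 of 40 cases against 5 higher, with a median of -0.19 (camera, adjusted p = 3.64e-05; adjusted p = 0.0282 with an estimated correlation).

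Tetrapyrrole synthesis genes were higher in flu toc33 dark in 19 of 27 cases and lower in 1, with a median of 0.21 (camera, adjusted p = 3.64e-05; adjusted p = 0.0174 with an estimated correlation). HEMA1, the first committed enzyme of the pathway, was higher by 0.57 ± 0.029 (SE), and PORB, a light-dependent protochlorophyllide oxidoreductase, was the lower one at -0.84 ± 0.0281. Light signalling genes were higher in 9 of 11 cases and lower in 2, with a median of 0.47 (camera, adjusted p = 5.67e-04; adjusted p = 0.0244 with an estimated correlation). Dark and starvation genes were higher in 13 of 15 cases and lower in 1, with a median of 0.39 (camera, adjusted p = 6.73e-06; adjusted p = 0.0244 with an estimated correlation). They included DIN6, an asparagine synthetase, at 1.02.

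Calls that were lost with an estimated correlation concerned the plastid most. Genes of light-harvesting proteins were lower in 14 of 18 cases and higher in 2, with a median of -0.89 (camera, adjusted p = 1.67e-09; adjusted p = 0.2 with an estimated correlation). They included LHCA1 at -1.10 ± 0.0337 (SE), LHCB3 at -1.45 ± 0.0518 and LHCB1.4 at -1.68 ± 0.058. Copies within the LHCB1 family are near-identical, so values of single copies are uncertain. Photosystem and electron transport genes were lower in 18 of 29 cases and higher in 2, with a median of -0.17 (camera, adjusted p = 4.69e-06; adjusted p = 0.301 with an estimated correlation). Plastid chaperone genes were higher in 7 of 12 cases, with a median of 0.20 (camera, adjusted p = 0.00495; adjusted p = 0.133 with an estimated correlation), and the call was also lost under quantile normalization, at 0.12 (adjusted p = 0.0649). Heat shock genes were lower in 8 of 17 cases and higher in 2, with a median of -0.21 (camera, adjusted p = 0.00862; adjusted p = 0.133 with an estimated correlation). Mitochondrial genome transcripts were lower in 10 of 38 cases and higher in 1, with a median of -0.27 (camera, adjusted p = 0.0195; adjusted p = 0.192 with an estimated correlation). That call was lost without flu dark replicate 2, at a median of -0.23 (adjusted p = 0.0597), without flu dark replicate 3, at -0.28 (adjusted p = 0.0698), and under quantile normalization, at -0.18 (adjusted p = 0.0649). The median depended on the filter, at -0.0991 with none (adjusted p = 0.127) and -0.77 at 5 TPM (adjusted p = 0.0975), where the call was lost too. Among the lists called in this comparison, counts adjusted over the list alone differed for the jasmonate list (1 higher), the early singlet oxygen list (23 lower), the photosystem list (19 lower), the tetrapyrrole list (2 lower) and the mitochondrial genome (6 lower).

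In total 8145 of 19667 genes differed between flu toc33 dark and flu dark by limma with Benjamini-Hochberg adjustment, 4118 higher and 4027 lower in flu toc33. That split turned without flu dark replicate 3, to 4032 higher and 4698 lower. It also turned by less with no filter on low values, at 4032 and 4135, in a fit of the compared groups alone, at 3214 and 3332, and without any 1 of the flu toc33 dark libraries. Of these, 500 differed at least 2-fold, 151 higher and 349 lower. The groups did not overlap in 49.5% of genes, against 10% by chance.

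After 1 h of light the genotypes differed in more genes. WRKY30 stood at 149 ± 5.41 TPM (SD, n = 3) in flu light and 2.97 ± 0.0619 TPM in flu toc33 light, TDR1 (AT3G23230), an ethylene response factor, at 90.0 ± 5.5 and 1.55 ± 0.32 TPM, PP2-B13 (AT1G56240) at 161 ± 5.45 and 3.85 ± 0.699 TPM and ERF105 at 164 ± 5.21 and 4.4 ± 2.99 TPM. AT2G22880 stood at 61 ± 8.68 TPM in flu light and was listed at 0 in the 3 flu toc33 light libraries. The defensin genes PDF1.2 and PDF1.2c stood at 76.2 ± 0.705 and 41.2 ± 2.99 TPM in flu light and at 0.796 ± 0.0976 and 0.187 ± 0.183 TPM in flu toc33 light. Higher in flu toc33 light were seed storage genes, such as SESA3 at 48.3 ± 3.5 against 0.111 ± 0.115 TPM, SESA2 at 23.5 ± 0.695 against 0.16 ± 0.189 TPM and CRU3 at 36.1 ± 1.74 against 1.31 ± 0.362 TPM. SESA1, SESA4 and CRU2 stood at 16.7 ± 0.661, 11.8 ± 1.8 and 11.1 ± 0.36 TPM in flu toc33 light, against 0.168 ± 0.146, 0.0984 ± 0.17 and 0.0274 ± 0.0475 TPM in flu light. The small heat shock gene HSP23.6 (AT4G25200) stood at 70.3 ± 1.63 against 5.41 ± 0.48 TPM. AT4G22520 stood at 17.1 ± 5.7 against 0.828 ± 1.43 TPM, and its log2 difference of 3.53 became 4.13 without flu light replicate 2.

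Of 40 early singlet oxygen genes 39 were lower in flu toc33 light and 1 was higher, with a median log2 difference of -2.67 (camera, adjusted p = 8.81e-25; adjusted p = 6.73e-04 with an estimated correlation). They included WRKY18 at -4.19 ± 0.0631 (SE), WRKY33 at -3.42 ± 0.0539 and TCH4 at -2.93 ± 0.0438. All 15 dark and starvation genes were lower, with a median of -1.999 (camera, adjusted p = 4.29e-12; adjusted p = 0.00357 with an estimated correlation), and 16 of 17 heat shock genes were higher, with a median of 1.79 (camera, adjusted p = 1.55e-08; adjusted p = 0.00885 with an estimated correlation). Jasmonate genes were lower in 21 of 25 cases and higher in 3, with a median of -1.15 (camera, adjusted p = 2.40e-08; adjusted p = 0.0217 with an estimated correlation), JAZ1, a repressor of jasmonate signalling, at -3.01. Salicylic acid and EDS1 genes were lower in 11 of 13 cases and higher in none, with a median of -1.02 (camera, adjusted p = 1.22e-05; adjusted p = 0.0217 with an estimated correlation), EDS1 at -1.86. Electrophile detoxification genes were lower in 16 of 21 cases and higher in 2, with a median of -0.93 (camera, adjusted p = 9.68e-07; adjusted p = 0.0069 with an estimated correlation). Plastid chaperone genes were higher in 10 of 12 cases and lower in 1, with a median of 0.75 (camera, adjusted p = 1.81e-05; adjusted p = 0.0371 with an estimated correlation), and all 7 flavonoid genes were higher, with a median of 1.63 (camera, adjusted p = 3.07e-04; adjusted p = 0.0371 with an estimated correlation). CPN60B2, a subunit of the plastid chaperonin, was higher by 1.88 and CHS by 2.05.

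Other lists passed with the preset correlation and were lost with an estimated one. Plastid protein import genes were higher in 16 of 21 cases and lower in 2, TOC33 included, with a median of 0.33 (camera, adjusted p = 0.0269; adjusted p = 0.284 with an estimated correlation). Tetrapyrrole genes were higher in 19 of 27 cases and lower in 6, with a median of 0.29 (camera, adjusted p = 0.0297; adjusted p = 0.0937 with an estimated correlation), a call that was also lost under quantile normalization, at 0.26 (adjusted p = 0.103), and median-ratio scaling, at 0.18 (adjusted p = 0.0794). PORB differed by -1.32 ± 0.0281 (SE) and HEMA2 by -1.70 ± 0.0529. Ethylene genes were lower in 12 of 15 cases, with a median of -0.96 (camera, adjusted p = 8.77e-06; adjusted p = 0.153 with an estimated correlation), and indole glucosinolate genes in 7 of 10, with 2 higher and a median of -0.91 (camera, adjusted p = 0.00975; adjusted p = 0.14 with an estimated correlation). Aliphatic glucosinolate genes were higher in 5 of 6 cases, with a median of 0.73 (camera, adjusted p = 0.0191; adjusted p = 0.188 with an estimated correlation), and light signalling genes in 8 of 11, with 2 lower and a median of 0.61 (camera, adjusted p = 0.0215; adjusted p = 0.0914 with an estimated correlation). Genes of light-harvesting proteins were lower in 13 of 18 cases and higher in 3, with a median of -0.55 (camera, adjusted p = 1.01e-04; adjusted p = 0.366 with an estimated correlation), and photosystem genes in 19 of 29, with 4 higher and a median of -0.27 (camera, adjusted p = 3.42e-04; adjusted p = 0.366 with an estimated correlation). Plastid genome transcripts were lower in 31 of 86 cases and higher in 13, with a median of -0.21 (camera, adjusted p = 0.0215; adjusted p = 0.546 with an estimated correlation), and that call was lost under median-ratio scaling, where the median was larger, at -0.30 (adjusted p = 0.064). All 6 root markers were higher, with a median of 0.69 (camera, adjusted p = 0.0268; adjusted p = 0.0968 with an estimated correlation), as were all 3 epidermis markers, with a median of 0.73 (camera, adjusted p = 0.0215; adjusted p = 0.276 with an estimated correlation). Among the lists called here, counts adjusted over the list alone differed for plastid chaperones (11 higher), tetrapyrrole genes (20 higher) and the plastid genome (12 higher).

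After reillumination 13140 of 19667 genes differed by limma with Benjamini-Hochberg adjustment, 7662 higher and 5478 lower in flu toc33, of which 2244 differed at least 2-fold, 713 higher and 1531 lower. The groups did not overlap in 74.0% of genes, against 10% by chance. Median-ratio scaling turned the split, to 6018 higher and 6919 lower.

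The interaction tested directly whether the light response differed between the genotypes, as the response in flu toc33 minus that in flu. WRKY30 rose from 0.854 to 149 TPM in flu and stood at 0.911 and 2.97 TPM in flu toc33, a log2 difference of -5.27 ± 0.164 (SE; limma, adjusted p = 1.54e-11). TDR1, PP2-B13 and AT4G33467 differed by -5.16 ± 0.142, -4.54 ± 0.169 and -4.47 ± 0.24. AT2G22880 and AT1G19040 were listed at 0 in every group except flu light, where they stood at 61 ± 8.68 and 19.96 ± 2.02 TPM (SD, n = 3). AT1G22810 stood at 30.1 ± 2.65 TPM in flu light and 0.291 ± 0.256 TPM in flu toc33 light, and ERF105 at 164 ± 5.21 and 4.4 ± 2.99 TPM, each being listed at 0 in flu toc33 dark. In the other direction, HSP17.4 differed by 4.00 ± 0.102, HSP23.6 by 3.79 ± 0.214, HSP22 (AT4G10250) by 3.35 ± 0.145, AT5G48570, an immunophilin gene, by 3.21 ± 0.0989, AT5G12110 by 3.23 ± 0.2 and UGT74E2 by 3.32 ± 0.0704. UGT74E2 stood at 18.7 and 45.1 TPM in flu dark and light and at 1.14 and 49 TPM in flu toc33 dark and light. HSP17.6II stood at 25.4 ± 1.31 TPM in flu light and 161 ± 1.89 TPM in flu toc33 light, and HSP21 (AT4G27670), a plastid small heat shock protein, at 0.343 ± 0.0972 and 10.8 ± 0.392 TPM, both listed at 0 in flu toc33 dark.

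Interaction values of the early singlet oxygen list were lower than 0 for 39 of 40 genes and higher for 1, with a median interaction of -2.43 (camera, adjusted p = 5.69e-25; adjusted p = 6.55e-04 with an estimated correlation). NAC102 differed by -2.66 ± 0.051 (SE), TCH4 by -2.76 ± 0.0619, WRKY18 by -3.52 ± 0.0893 and ERF1A by -2.30 ± 0.063. Those of the heat shock list were higher for 16 of 17 genes and lower for 1, with a median of 2.03 (camera, adjusted p = 9.88e-10; adjusted p = 0.00767 with an estimated correlation), and HSP70 and HSP90.1 differed by 2.03 ± 0.0671 and 2.43 ± 0.0825. Those of the dark and starvation list were lower for 14 of 15 genes and higher for 1, with a median of -2.38 (camera, adjusted p = 9.89e-13; adjusted p = 0.00299 with an estimated correlation), AKINBETA1 at -3.11 ± 0.0521 and DIN6 at -3.13 ± 0.0811.

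Further lists passed only with the preset correlation. All 7 flavonoid genes had higher interaction values, with a median of 1.35 (camera, adjusted p = 1.76e-04; adjusted p = 0.0512 with an estimated correlation), as had all 6 aliphatic glucosinolate genes, with a median of 1.81 (camera, adjusted p = 3.47e-05; adjusted p = 0.0609 with an estimated correlation). CHS differed by 2.22 ± 0.0607 (SE) and CYP83A1 by 1.85 ± 0.0661. Plastid chaperone genes were higher in 10 of 12 cases and lower in 1, with a median of 0.57 (camera, adjusted p = 3.15e-04; adjusted p = 0.0899 with an estimated correlation). HSP21 is a member of both the plastid chaperone and the heat shock list. Jasmonate genes were lower in 16 of 25 cases and higher in 5, with a median of -0.71 (camera, adjusted p = 0.00397; adjusted p = 0.215 with an estimated correlation), JAZ1 and LOX3 at -2.02 ± 0.097 and -1.82 ± 0.092. Ethylene genes were lower in 11 of 15 cases and higher in none, with a median of -0.54 (camera, adjusted p = 3.12e-04; adjusted p = 0.332 with an estimated correlation), ERF2 and ACS6 at -1.93 ± 0.103 and -1.45 ± 0.0915. The salicylic acid and EDS1 list did not pass, with 8 of 13 genes lower and 2 higher and a median of -0.53 (camera, adjusted p = 0.0845; adjusted p = 0.332 with an estimated correlation). Nor did electrophile detoxification at a median of 0.0462 (camera, adjusted p = 0.889), light signalling at 0.0756 (adjusted p = 0.889) or the clock at -0.013 (adjusted p = 0.889). Root markers, at 0.92 (camera, adjusted p = 0.0617; adjusted p = 0.171 with an estimated correlation), passed with the preset correlation without flu dark replicate 1, at 0.97 (adjusted p = 0.0466), without flu toc33 light replicate 3, at 0.97 (adjusted p = 0.0458), under median-ratio scaling, at 0.85 (adjusted p = 0.0246), and with a pseudocount of 0.1 TPM, at 1.35 (adjusted p = 0.0418). Counts adjusted over the list alone were the same for all lists given for the interaction.

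**Figure D3:**
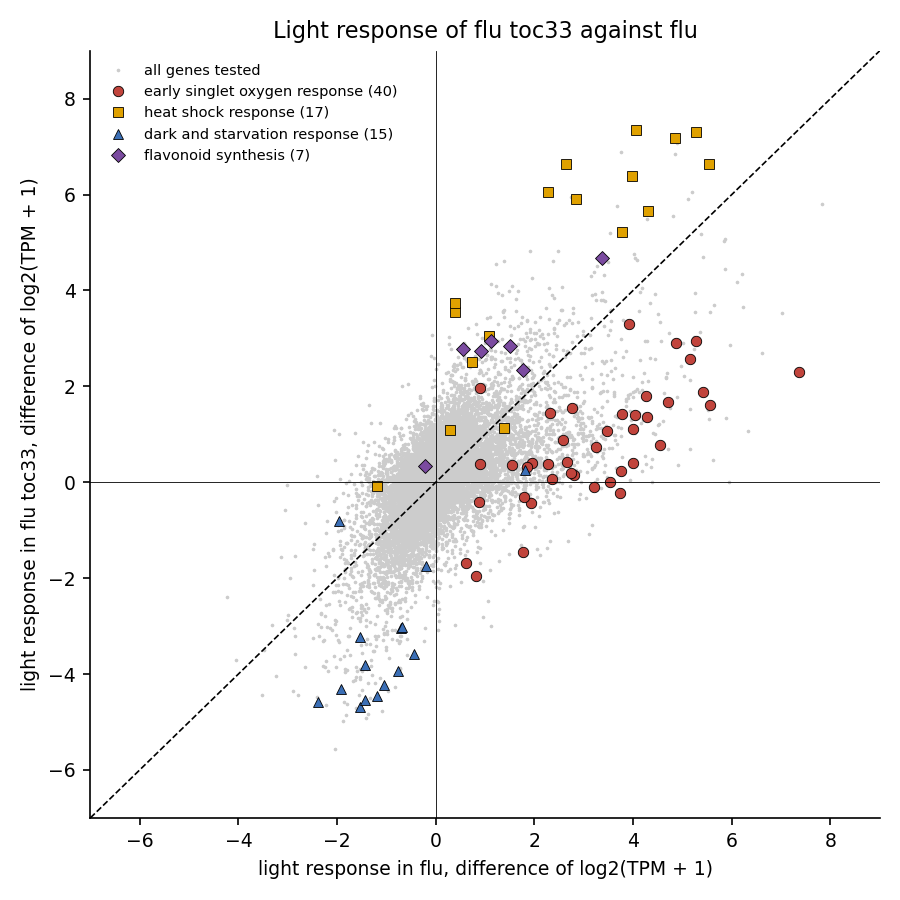
Light response in flu toc33 against that in flu for the 19667 genes tested, each axis the difference of mean log2(TPM + 1) between light and dark; the dashed line marks equal responses. Coloured points are members of 4 gene lists, with numbers of genes in brackets; the early singlet oxygen genes have a median of 3.23 in flu and 0.58 in flu toc33, the heat shock genes 2.64 and 5.65.

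The light response differed between genotypes in 11151 of 19667 genes by limma with Benjamini-Hochberg adjustment, 6220 with a higher and 4931 with a lower value in flu toc33, and in 2335 genes the difference was at least 2-fold, 890 higher and 1445 lower. Median-ratio scaling turned the split of all calls, to 4915 higher and 6186 lower. Of the 1799 genes that rose at least 2-fold in flu, 1253 rose less in flu toc33 by the interaction test, 826 of them by at least 2-fold less, and 276 rose more. Selection in flu favours smaller values in the other genotype: of the 1798 genes that rose at least 2-fold in flu toc33, 1172 rose less in flu and 355 rose more. Of the 1349 genes that fell at least 2-fold in flu toc33, 1134 fell less in flu and 38 fell more, while of the 713 that fell in flu 291 fell less in flu toc33 and 269 more. Rises of at least 2-fold in both genotypes numbered 849, where independent lists would share 164, and falls in both 427, where 48.9 would be shared. Across genes the light responses of the genotypes correlated at a Pearson r of 0.638 and a Spearman rho of 0.632, where genes are not independent replicates. The genotype differences in dark and light correlated at 0.293 and 0.174, and 69 genes were at least 2-fold higher and 156 lower in flu toc33 in both, where independent lists would share 5.47 and 27.2.

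The mean light response over both genotypes picked genes without favouring one. It called 14723 genes by limma with Benjamini-Hochberg adjustment, 7857 up and 6866 down, and 2464 at least 2-fold, 1606 up and 858 down. Quantile normalization turned the split of all calls, to 6631 up and 8478 down. Over the 1606 rising genes the median log2 response was 1.77 in flu and 1.45 in flu toc33, and 56.4% responded less in flu toc33. Their slope of the flu toc33 response on that of flu was 0.647 ± 0.0353 (jackknife SE over libraries). Slopes were fitted through the origin with flu as predictor. Scatter of genes between the genotypes lowers such a slope, so it does not treat the genotypes alike. Over the 858 falling genes the medians were -1.07 and -1.74, 17.7% responded less in flu toc33, and the slope was 1.399 ± 0.0196. These values for falling genes depended on the pseudocount: 23.0% and a slope of 1.15 with 0.1 TPM, and 11.5% and a slope of 1.58 with 5 TPM. Early singlet oxygen genes rose in 37 of 40 cases on average and fell in 2, with a median of 1.82 (camera, adjusted p = 6.30e-13; adjusted p = 0.00683 with an estimated correlation), and light signalling genes in 10 of 11, with 1 lower and a median of 2.01 (camera, adjusted p = 2.12e-05; adjusted p = 0.00704 with an estimated correlation). Counts adjusted over the list alone were the same for both.

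Some lists were not called in any of the 4 comparisons of groups nor in the interaction. Genes of singlet oxygen signalling components had medians of 0.11 in flu and 0.19 in flu toc33 for the light response (camera, adjusted p = 0.284 and 0.434), although the kinase gene OXI1 rose by 4.50 ± 0.0934 (SE) and 3.52 ± 0.0934. Calvin cycle genes had medians of -0.0418 and -0.0788 (camera, adjusted p = 0.726 and 0.434), and antioxidant enzymes -0.0511 and 0.11 (camera, adjusted p = 0.703 and 0.56), where VTC2, an enzyme of ascorbate synthesis, rose by 2.05 ± 0.0414 and 2.90 ± 0.0414. In flu light the median of the antioxidant list was below 0 and its mean, 0.21, above 0. Guard cell markers had medians of -0.0511 and -0.0754 (camera, adjusted p = 0.864 and 0.984) and vascular markers -0.12 and -0.10 (camera, adjusted p = 0.453 and 0.434). Tetrapyrrole and import genes were not called for light in either genotype, with medians of -0.13 and -0.0912 (camera, adjusted p = 0.453 and 0.434) and of -0.0887 and 0.061 (camera, adjusted p = 0.361 and 0.984). Where median, mean and test of a list differed in sign, the list was not called; in the interaction the indole glucosinolate list had a median of 0.34 and a mean of -0.14 (camera, adjusted p = 0.892). The Calvin cycle list was called in flu toc33 dark against flu dark under quantile normalization alone, at a median of 0.18 (adjusted p = 0.0174). The antioxidant list, with a median of 0.30 in flu toc33 light against flu light (camera, adjusted p = 0.0672), was called there with no filter on low values alone (adjusted p = 0.0388). Indole glucosinolate genes, not called in flu light against flu dark, were called there without flu dark replicate 2, at a median of 0.64 (adjusted p = 0.0475), and without replicate 3, at 0.58 (adjusted p = 0.0317). Epidermis markers were called in the interaction without flu dark replicate 3 alone, at 0.60 (adjusted p = 0.0241).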

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

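The tests of mixed samples, of intact TOC33 seedlings, of a weaker light response as a whole, of tetrapyrrole transcripts and of different conditions were chosen after the results were seen; those of TOC34 and of scaling were written before the values they rest on were seen. The results given here stand out because the interaction test found a different light response in the 2 genotypes.

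In all, 11151 genes had a different light response by limma with Benjamini-Hochberg adjustment. Splits of the libraries that shuffled the genotypes within each treatment were drawn. Of 100 splits 1, the real one, called 11151 genes, and the highest of the others called 8785. Such splits remove every genotype effect and not the interaction alone, so they cannot tell whether chance gave that number. For the mean light response the treatments were shuffled within each genotype. The real split, 1 of 100, called 14723 genes, and the highest of the others 8840. In either case, swapping the labels throughout would call as many genes, and no such split was drawn. For the comparisons of 2 groups only 10 splits exist, too few for a share under 0.05. The real split, 1 of the 10, called 12118 genes for flu light against flu dark, where the highest other called 1, and 13964 for flu toc33 light against dark, where it called 0. It called 8145 for the genotypes in the dark, where the highest other called 1, and 13140 in the light, where it called 0. The other splits mix real groups, here and for the mean light response, so the real difference enters the spread. Their counts therefore do not show how many genes chance would call.

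The median interaction of the early singlet oxygen list was -2.43 on the log2 scale, with 39 of 40 genes lower. A weaker response of flu toc33 to light in all genes alike is argued against by the dark and starvation list. Its interaction median of -2.38 means a larger fall in flu toc33. That list holds mostly falling genes, so it does not argue against a weaker response of rising genes. Over the 1606 genes that rose in the mean light response the median was 1.77 in flu and 1.45 in flu toc33, and 56.4% responded less in flu toc33. Lower transcripts of tetrapyrrole synthesis before the light are argued against by that list's median of 0.21 in flu toc33 dark against flu dark, although transcripts do not measure protochlorophyllide or singlet oxygen. The scaling of TPM is argued against by the median of -2.47 after quantile normalization. Different illumination or harvest of the genotypes cannot be told apart from an effect of toc33-1, since the heat shock list moved the other way by 2.03 and no library separates condition from genotype. No test here separated a weaker response to singlet oxygen without TOC33 from a lower amount of singlet oxygen in flu toc33, so both stay open as hypotheses. The interaction also takes flu toc33 dark and light as like material, which was not tested. TOC33 stood at 48.7 and 3.97 TPM in these 2 groups, and seed storage transcripts differed between them too.

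TOC33 itself had an interaction of -3.08, because flu toc33 dark held 23.9% of the flu dark level and flu toc33 light far less. Mixing of flu dark RNA into the flu toc33 dark libraries is argued against by 5 genes, PDF1.3, PDF1.2, PDF1.2c, AT3G22235 and PR1. They kept 0.44% to 2.45% of their flu dark level. The same genes argue against seedlings with an intact TOC33 and the transcripts of flu among those sampled. The bar of 5 genes was set after the results were seen, and the defensin genes among them are near-identical copies. Intact seedlings that lacked only these transcripts are not argued against. Reads of TOC34 are argued against by the size of that gene's change in the light, a log2 of 0.44, from 28.9 to 39.5 TPM. TOC33 fell from 48.7 to 3.97 TPM. The opposite direction of the 2 genes does not decide, since reads taken from TOC34 in the dark would give it too. TOC34 stood at 30.6 TPM in flu dark and 28.9 TPM in flu toc33 dark (limma, adjusted p = 0.367). Reads taken from it would have lowered it there, unless its own transcript had risen. Seedlings with an intact TOC33 but otherwise the transcripts of flu toc33 cannot be told apart from a leaky transcript of toc33-1 by the 23.9%, since no sequence of the allele was analysed here. A residual transcript of the allele that light or stress lowers may be offered only as an untested explanation.

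Other lists with a different light response were dark and starvation at a median of -2.38 and heat shock at 2.03, both also called with an estimated correlation. Called with the preset correlation alone, and not with the estimated one, were aliphatic glucosinolate synthesis at 1.81, flavonoid synthesis at 1.35, jasmonate at -0.71, plastid chaperones at 0.57 and ethylene at -0.54. Single genes with higher interaction values were HSP17.4 at 4.00, HSP23.6 at 3.79, HSP22 at 3.35, UGT74E2 at 3.32, AT5G12110 at 3.23 and AT5G48570 at 3.21, and HSP17.6II and HSP21 reached 161 and 10.8 TPM in flu toc33 light from a group listed at 0. The value of UGT74E2 came mainly from its lower level in flu toc33 dark than in flu dark. Genes with lower interaction values were WRKY30 at -5.27, TDR1 at -5.16, PP2-B13 at -4.54 and AT4G33467 at -4.47. AT2G22880, ERF105, AT1G22810 and AT1G19040 reached 61.0, 164, 30.1 and 19.96 TPM in flu light and have a group listed at 0.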

How the results depend on the processing

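The alternatives were planned, and no test here was chosen after the results were seen. Transcripts tested singly and the 2-fold threshold were run for the numbers of genes called alone. Over the rest, with the preset correlation, 3312 of 3362 list results kept their direction and side of the threshold, 40 lost and 10 gained a call. The estimated correlation, not among these settings, left 5, 5, 9, 8, 3 and 6 of 12, 11, 14, 19, 8 and 12 called lists. The order is that of the 4 comparisons of groups, the interaction and the mean response. Of 12779 results for named genes 12622 kept their direction and side of the threshold, 117 lost a call, 36 gained one and 4 turned in sign or reached 0. These 4 came under quantile normalization, for RBCS3B (AT5G38410) and RBCS2B (AT5G38420), near-identical genes of the small Rubisco subunit. In flu light against flu dark RBCS3B stood at 0.21 (limma, adjusted p = 0.0154), the only called result with a turned sign, and RBCS2B at 0.0756 (adjusted p = 0.184). In flu toc33 dark against flu dark RBCS3B stood at 0, with no direction, and RBCS2B at 0.0789 (adjusted p = 0.208). That normalization fixes the values of the most abundant genes, and the cause was not tested further. Requiring a 2-fold change left 2512, 3147, 500, 2244, 2335 and 2464 genes, in the order flu light, flu toc33 light, genotype in the dark, genotype in the light, interaction and mean response, since that threshold removes small changes. Leaving out 1 library gave 11029 to 12792, 13165 to 14782, 6896 to 8730, 12086 to 14220, 10312 to 12209 and 14122 to 15259 genes in that order. With the replicate number as a block 11944, 13861, 7904, 12936, 10948 and 14576 genes were called; the numbers do not pair the libraries, since correlations of the 18 same-numbered pairs ran from -0.17 to 0.12 and only 3 of 12 libraries correlated best with their own number. For falling genes the slope of the flu toc33 on the flu response was 1.15 and 1.58 with pseudocounts of 0.1 and 5 TPM, 1.42 with the filter at 5 TPM, 1.33 after quantile normalization and 1.46 after median-ratio scaling. The percent responding less was 23.0, 11.5, 20.1 and 15.5 for these settings without the filter, and for rising genes it was 59.8 after median-ratio scaling; the cause was not tested. Without 1 library the slopes ran from 0.643 to 0.672 for rising and 1.385 to 1.405 for falling genes, and the percents from 54.7 to 57.2 and 17.0 to 18.1. Depth is unknown for TPM, so a gene listed at 0 cannot be given a limit of detection.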

Other observations

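The test of a single library was chosen after the seed storage values were seen; the list of oleosin and embryo genes was written before its values were seen. The seed storage genes CRA1 and CRU3 were looked at after their values were seen. CRA1, a cruciferin, was present in every group, at 47.0, 45.0 and 48.3 TPM in the flu dark libraries and 210, 65.1 and 146 TPM in the flu toc33 dark libraries. In the light it stood at 20.3, 20.1 and 16.2 TPM in flu and at 47.0, 48.1 and 45.6 TPM in flu toc33. CRU3 stood at 196, 44.6 and 142 TPM in flu toc33 dark. Replicate 2 was the lowest of the flu toc33 dark libraries for both genes.

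The seed transcripts may come from seed or embryo tissue, such as seeds that had not germinated, in the flu toc33 samples. Of 12 oleosin and embryo genes, 12 were higher in flu toc33 dark than in flu dark by limma with Benjamini-Hochberg adjustment, and 11 in flu toc33 light than in flu light, as that hypothesis predicts. Over all genes tested, 4118 of 19667 were called higher in flu toc33 dark and 7662 in flu toc33 light. EM1 was near the floor in the dark (limma, adjusted p = 0.0468). It stood at 0.157, 0.782 and 0.0968 TPM in flu dark and 0.712, 0.962 and 0.873 TPM in flu toc33 dark, so the groups overlapped. Seed tissue of 1 kind as the source of all these transcripts is not shown, since the genes did not move alike. From flu toc33 dark to light 7 of the 12 rose and 3 fell, while all 7 seed storage genes fell by a log2 of 1.26 to 3.04. The genes that rose were EM1, GEA6, AT3G15670, ECP63, LEA7, AT3G17520 and AT2G25890, by 0.55 to 1.43. CRA1 and CRU3 changed from dark to light in flu too, by -1.27 and -3.13 (limma, adjusted p = 0.00142 and 4.9e-06). For them a fall in the light is thus not particular to flu toc33. GEA6 and AT2G25890 also lacked the deep drop of the storage genes in flu toc33 dark replicate 2, AT2G25890 standing at 4.27, 3.90 and 4.32 TPM. EM1 lacked it too, but stayed below 1 TPM. These genes were looked at after their values were seen. A single library is argued against as the source, since the lowest flu toc33 dark library stood 27.4 times above the highest flu dark library, or above 1 TPM where that was more, in the median of the seed storage genes. Seedlings that lost seed transcripts later in flu toc33, as a biological difference between the genotypes, stay open and were not tested. The report's comparisons of genotypes hold these transcripts too, as do the flu toc33 light response and the interaction. TOC33 also differed between flu toc33 dark and light, at 48.7 and 3.97 TPM. Whether the dark and light flu toc33 samples held like material was not tested.

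LEA7, of that list, was the exception in the light, at 28.3, 30.1 and 32.1 TPM in flu light and 18.4, 19.99 and 19.3 TPM in flu toc33 light.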
